A study of Mus musculus with 12 samples.

How the data were processed

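Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on livers of male C57/BL6 mice aged 12 to 14 weeks, kept under a cycle of 12 h light for 7 days before collection, per the labels' protocols. The labels give 5 mice at a first time (Zeitgeber time 2 h, counted from lights on) and 5 mice at a second time (26 h) that serve as the biological replicate. They do not say which replicate number belongs to which time, nor whether mice were pooled. The p-values therefore measure only the spread between libraries of a group, pooled over all 6 groups. Per the same protocols, libraries had fragments of about 250 bp and were made with 15 PCR cycles.

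The 12 libraries form 6 groups of 2, taken from the titles. RPC1 and RPC4 are subunits of RNA polymerase III (Pol III), RPB2 is a subunit of RNA polymerase II (Pol II), and input is chromatin without immunoprecipitation. The labels of the 4 histone libraries disagree with themselves. The 2 libraries titled H3K4 have an antibody field naming H3K36me3, and the 2 titled H3K36 have an antibody field naming H3K4me3. They are called H3K4-titled and H3K36-titled throughout, after titles and track headers.

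The deposited files hold coverage, a signal per base that the authors did not scale for depth as far as the values show: a read lying alone adds 1.0 over 76 bp, and file totals differ. Per the submitters' processing notes the build is mm9. The aligner, read filter and any weighting of reads are not given in the sources used here. Fractional values occur where reads seem to have been divided among several places. Each deposited file lists coverage over the same 532 stretches, 370 to 1170 bp long (median 373 bp). All ends lay within the chromosome lengths of the NCBIM37 (mm9) reference. A further stretch on the X chromosome was listed in some files only and was left out. The number of reads outside these stretches is unknown, so no library's full depth is known.

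Gene identities came from the GENCODE vM1 annotation of the same build and from a cloverleaf search written for this work, which required at least 17 base pairs in the 4 stems of a tRNA. In stretches with room for a single gene, a cloverleaf was accepted only if its ends lay exactly 150 bp from both ends, and 343 of 392 held such a one. In other stretches more pairs were required. The search placed at least 1 tRNA gene in 365 stretches, 384 genes in all. The tRNA names, with the anticodon in parentheses, are therefore predicted and not annotated, and the printed coordinates are gene plus flanks of 150 bp. That annotation named 50 stretches as 5S rRNA genes, 5 as U6, 2 as Y RNA, and 1 each as U6atac, 7SK and RNase MRP RNA. Another 103 stretches matched neither source under these rules. In the GRCm38.p6 RefSeq table, used for neighbours only, the nearest RNase P RNA gene to Parp2 is Rpph1, and the nearest 7SL genes to Rps29 and Nemf are Rn7s1 and Rn7s2. 3 short RNA genes beside Parp2, Rps29 and Nemf in the mm9 annotation are described by these neighbours. SINE elements were not annotated here, and no stretch was predicted to hold the selenocysteine tRNA. The liver Pol II genes considered for a check of the labels were not covered by the files.

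Stretches under 1000 bp apart were merged into 442 regions, and each region's value was its mean coverage over covered bases. Values were tested on the log2(scaled coverage + pseudocount) scale with limma 3.58.1 in R 4.3.3, with a mean-variance trend, all 12 libraries in 1 fit (6 residual degrees of freedom) and 1 coefficient per group. Each region thus had 1 estimate of spread from all 6 groups, although replicates of some groups varied far more. The median absolute log2 difference between replicates was 0.194 for RPC1, 0.218 for RPC4, 0.502 for input and 1.02 for H3K36-titled libraries. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The pseudocount, 0.0877 with file totals and 0.153 with the anchored scaling, was the 5th percentile of nonzero scaled values, and it shrinks fold changes of low regions. Regions under the 0.1 quantile of mean coverage were left out, which left 397.

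The design fixed before the data were examined scales by file totals when files hold no background away from Pol III summits, which was the case. Then "above input" means a larger share of the file than in input, and a Pol III library whose reads lie mostly in strong regions pushes all other regions below input. A background-anchored scaling was therefore added after the data had been seen. It divides each library by the 10% trimmed mean (trim 0.1) over the 25% of regions with the lowest Pol III coverage. This assumes that those regions are unenriched in every library, and it uses Pol III itself to set the zero, so its counts are given beside the planned ones and never in their place. Regions counted as occupied by Pol III are those above input in the fit with file totals, unless the anchored fit is named.

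The same functions were tested on simulated data with the real depths, a coefficient of variation of 0.15 between libraries and 20 regions at each of 3 fold sizes. With no difference simulated, Pol III, RPB2, H3K4-titled and RPC1 against RPC4 gave 0 calls and H3K36-titled gave 1, of 397 regions each. In the simulated Pol III comparison (397 regions), 3 of 14 tested regions with a 2-fold difference, 7 of 13 with a 4-fold and 8 of 10 with a 16-fold difference were recovered, with 0 of 360 unchanged regions called. In the simulated RPC1 and RPC4 comparison (397 regions) the recovered numbers were 3 of 20, 6 of 20 and 15 of 20 in the same order. For RPB2 (397 regions) they were 2 of 16, 5 of 17 and 7 of 13. In both, 0 unchanged regions were called (of 337 and 351). For H3K4-titled (397 regions) they were 5 of 20, 8 of 20 and 14 of 18, with 1 of 339 unchanged regions called. For H3K36-titled (397 regions), 1 of 17, 5 of 15 and 11 of 13 were recovered, and 6 of 352 unchanged regions were called. Those simulations kept the file totals balanced, a design adopted after an earlier one with equal numbers of rises and falls gave false calls. With equal rises and falls, which shift the file totals, unchanged regions called were 3 of 348 for Pol III, 5 of 338 for RPC1 against RPC4, 4 of 343 for RPB2, 1 of 341 for H3K4-titled and 17 of 339 for H3K36-titled (397 regions each). Most were called lower, 16 of the 17 for H3K36-titled. A further simulation of the Pol III comparison (397 regions) gave Pol III libraries the folds of the anchored fit. With file totals, 83 of 282 enriched regions were called above input, 90 were called below, and 114 of 115 unenriched regions were called below. With the anchored scaling, 279 of 284 enriched and 0 of 113 unenriched regions were called above. This shows how file totals act on such libraries, not which scaling is right for the real ones.

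Differences between occupied and other regions are differences of median log2 enrichment over mean input, per library, and no p-value was computed for these. Correlations are Spearman's rho across occupied regions, which are not independent replicates, so no p-value is given. 3 such correlations were computed. Because both quantities share the input libraries, each rho stands beside its value without division by input and beside the mean of 200 simulations with no effect. It was also computed with the 2 input libraries divided between the quantities, averaged over both assignments, although occupied regions were still called with both. Distances are medians over occupied regions of the distance between a library's maximum and the Pol III summit after smoothing over 50 bp. Permutation tests used 100000 resamples (NumPy 2.4.6, SciPy 1.17.1, Python 3.11.15).

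The regions named were chosen by a rule fixed in advance: the 10 occupied regions with the highest Pol III coverage, the 5 occupied regions with the smallest fold, the 5 largest significant differences between RPC1 and RPC4 in each direction, the 5 largest significant folds of RPB2, H3K4-titled and H3K36-titled signal, and the 5 highest occupied regions among those below the median input value for both RPB2 and H3K4-titled signal. tRNA groups by amino acid, 5S genes, genes with a type 3 promoter, 7SL genes and each chromosome were fixed groups. Not every member is described. 1 fixed gene group is not reported here. Other settings chosen before the files were read were another scaling (median of ratios), no filter, a replicate block, leaving out each library, fitting only the groups compared, a window of 150 bp around the summit, a fold threshold, a doubled pseudocount and merging at 200 bp. File totals, also listed there as another scaling, were already the scaling in use. Added after seeing the data were the anchored scaling, unscaled coverage, divided input libraries, and the anchored scaling with a block, with merging at 200 bp and without each library.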

Results

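The series measured, in mouse liver, how much Pol III, Pol II and 2 histone marks lay on genes that Pol III transcribes, and asked which of these genes Pol III occupies. 12 ChIP-seq libraries were compared: RPC1 and RPC4 for Pol III, RPB2 for Pol II, H3K4-titled, H3K36-titled and input, each with n = 2. Libraries differed widely in depth over the 532 stretches. The Pol III libraries held 82276 to 160705 read equivalents of 76 bp, H3K4-titled libraries 17033 and 26665, RPB2 libraries 14779 and 13849, input 3563 and 3365, and H3K36-titled libraries 1754 and 1273. A median region held 6.05 and 6.01 reads in the 2 input libraries and 1.80 and 1.16 reads in the H3K36-titled libraries. Small differences were seldom detected in simulations at the real depths, where 1 of 17 regions with a 2-fold H3K36-titled difference was recovered. Replicates ranked the 442 regions alike in the Pol III libraries (Spearman's rho 0.978 for RPC1 and 0.984 for RPC4, across regions) and much less in input (0.395) and H3K36-titled libraries (0.354).

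The first comparison asked which regions hold more Pol III than input. Pol III coverage per region ran from 0.0790 to 237.4 reads per base (mean of 4 libraries), at a median input coverage of 1.03. The 10 occupied regions with the highest coverage all held tRNA genes, which code for the adaptors of translation. With file totals as the scale, limma called 88 of 397 regions above input and 211 below. With the background-anchored scaling, chosen after seeing the data, 284 of 397 were above and 0 below. Median-of-ratios scaling gave 113 above and 139 below, and coverage as deposited, also added later, gave 289 above and 1 below. A planned fit of only the Pol III and input libraries, with file totals, gave 124 above and 237 below. The number of occupied regions thus depended on the scaling and on which libraries were fitted.

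**Figure D1:**
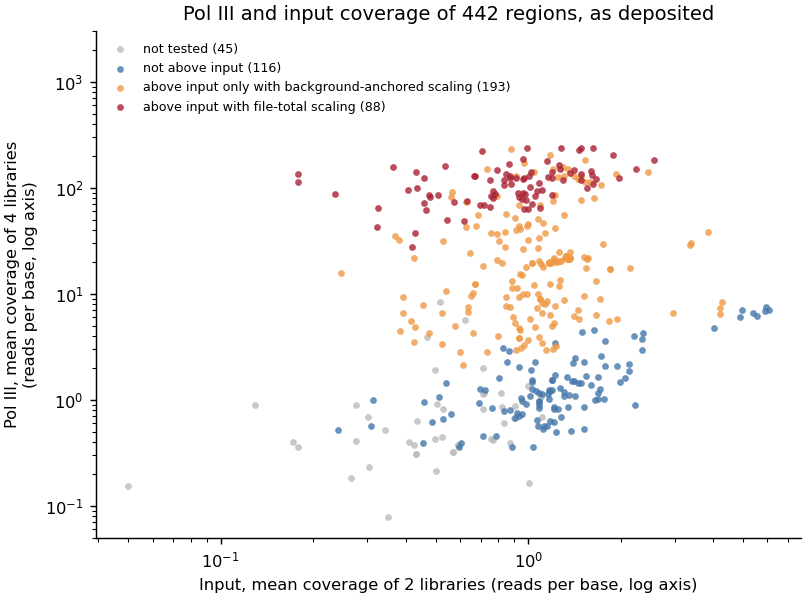
Mean Pol III coverage (4 libraries) against mean input coverage (2 libraries) for each of 442 regions, both in reads per base as deposited and on log axes; 1 region with lower input is drawn at 0.05. Colours separate the 88 regions above input with file totals, further regions above input only with the background-anchored scaling, tested regions above in neither, and regions not tested; input spans a narrower range than Pol III.

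The region with the highest Pol III coverage held a predicted tRNA-Arg (ACG) gene on chromosome 9 (mm9, 123438393 to 123438765, intergenic, 421 bp from the start of Sacm1l). Its coverage was 237.4 ± 54.3 reads per base (SD, n = 4) against 1.63 ± 0.0019 in input (SD, n = 2). Next came a region with a tRNA-Tyr (GTA) gene on chromosome 5 (31190306 to 31191110, 143 bp from the start of Agbl5) with 236.4 ± 92.6 (SD, n = 4), a pair of tRNA-His (GTG) genes on chromosome 2 (122202949 to 122203925) with 235.9 ± 72.1 (SD, n = 4), and a tRNA-Ser (GCT) gene on chromosome 2 (118872336 to 118872717, 329 bp from the start of Casc5) with 235.9 ± 71.5 (SD, n = 4). These SDs include the difference in coverage level between RPC1 and RPC4 libraries. The other 6 of the 10 highest occupied regions held tRNA genes for Glu and Leu, Arg, Phe and Asn, Arg, Asn and Thr, with Pol III coverage from 177.5 to 228.0. A tRNA-Met region at 231.0 was not called with file totals and so is not among them. The log2 fold over input of the tRNA-Arg (ACG) region on chromosome 9 was 2.13 (SE 0.68, adjusted p = 0.0202) with file totals and 7.15 (SE 0.43, adjusted p = 4.93e-09) with the anchored scaling.

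At the other end of the occupied regions, the smallest fold was at a pair of tRNA-Ala (CGC) and tRNA-Gly (GCC) genes on chromosome 2 (57034339 to 57035025). Its Pol III coverage was 64.6 ± 19.6 (SD, n = 4) and its log2 fold with file totals was 0.83 (SE 0.28, adjusted p = 0.0259). The other 4 regions of this list were a Y RNA region on chromosome 6, a region with tRNA-Val (CAC) and tRNA-Arg (ACG) genes on chromosome 13, an unmatched region on chromosome 6 and a tRNA-Arg (CCT) region on chromosome 17, with log2 folds of 0.92 to 0.93. With file totals, 5 occupied regions had the highest Pol III among those with RPB2 and H3K4-titled values below the median input value. They were a tRNA-Gly (GCC) gene on chromosome 11 (68932146 to 68932516) with Pol III coverage of 127.1 ± 26.4 (SD, n = 4), a region with tRNA-Asp (GTC) and tRNA-Ala (TGC) genes on chromosome 5, the 7SK gene, a tRNA-Cys (GCA) gene on chromosome 6 and a tRNA cluster on chromosome 13. With the anchored scaling, all of these but the tRNA-Cys region were above input for both signals. The tRNA-Gly region then had log2 folds of 1.57 for RPB2 (SE 0.44, adjusted p = 0.0116) and 4.11 for H3K4-titled signal (SE 0.44, adjusted p = 1.71e-06). At the 7SK gene the H3K4-titled call was weak, with coverage as deposited of 0.207 against 0.964 in input. Its H3K4-titled log2 fold in limma was 0.91 (SE 0.37, adjusted p = 0.0416) when anchored. With file totals it was -4.07 (SE 0.37, adjusted p = 5.93e-05), so the scaling turned its direction.

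Among 247 tested regions with a tRNA gene, 71 were above input and 108 below with file totals. With the anchored scaling, 164 of 250 were above. Adjusted over the list alone, the counts above input were also 71 and 164. Each of the 20 amino acids had at least 1 region above input under both scalings, counting regions that hold genes for several amino acids. Regions with only tRNA-Gln, tRNA-Met, tRNA-Phe or tRNA-Trp genes had 0 calls above input with file totals and 5, 3, 2 and 4 with the anchored scaling. Their highest Pol III coverage was 136.4, 231.0, 50.9 and 204.2 reads per base in the same order, so these 0 calls do not show low occupancy. tRNA-Arg regions had the highest median Pol III coverage of the single amino acid groups (105.4 reads per base over 16 regions), and 8 of 15 tested were above input with file totals and 13 of 15 with the anchored scaling (8 and 13 adjusted over the list alone). tRNA-Cys regions were the most numerous and nearly all low. Their median coverage was 1.16 over 46 regions, and 3 of 44 were above input with file totals, 39 of 44 below, and 6 of 43 above with the anchored scaling (3 and 6 adjusted over the list alone). The highest tRNA-Cys region, on chromosome 11 (97849410 to 97850458, 1837 bp from the start of Plxdc1), had 163.7 ± 63.1 (SD, n = 4) and was chosen after its values were seen. The 22 regions with only tRNA-Ala genes had a median of 0.460, and 9 of them passed the filter on low coverage.

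**Figure D2:**
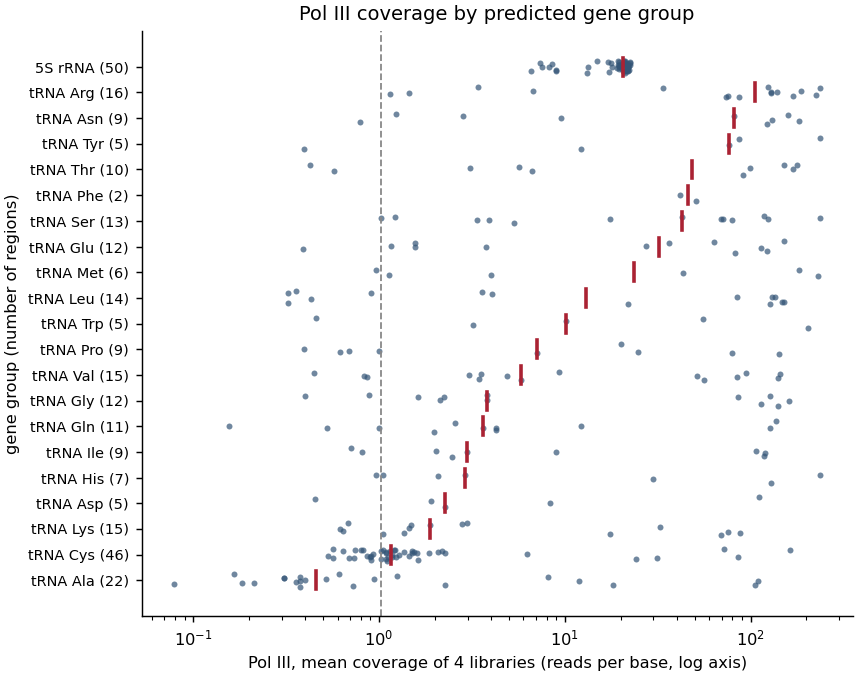
Pol III coverage (mean of 4 libraries, reads per base, log axis) of regions with genes for a single amino acid and of 5S rRNA regions, 1 point per region, with the group median as a red bar and the median input coverage of all regions (1.03) as a dashed line. Most groups spread from the input level to above 100, tRNA-Cys regions gather near the input level, and the 50 5S regions lie between 6.6 and 22.6 with a median of 20.7.

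The 50 5S rRNA genes, the only genes with a type 1 promoter, lay close together on chromosome 8 and had Pol III coverage of 6.6 to 22.6 (median 20.7). With file totals 0 of 50 were above input and 45 were below, whereas with the anchored scaling 50 of 50 were above, so the scaling turned the direction for these genes (0 and 50 adjusted over the list alone). Of the bases in 5S stretches, 98.0% had fractional coverage, against 9.84% in all other stretches, so values of single copies could not be separated.

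Of 9 regions with type 3 promoter genes (7SK, U6, RNase MRP RNA, Y RNA and the gene by Parp2), 4 were above input with file totals and 9 with the anchored scaling (4 and 9 adjusted over the list alone). The 7SK gene, whose RNA restrains the elongation factor P-TEFb, lay on chromosome 9 (78022960 to 78023590, intergenic) with Pol III coverage of 89.7 ± 21.1 (SD, n = 4) and a log2 fold of 1.48 (SE 0.32, adjusted p = 0.00338) with file totals. The RNase MRP RNA gene, which functions in rRNA processing, lay on chromosome 4 (43505510 to 43506080, overlapping an exon of Ccdc107, 23 bp from the start of Ccdc107) with 92.6 ± 24.4 (SD, n = 4; adjusted p = 0.00164). The gene by Parp2, in the place of the RNase P RNA gene, had 10.8 ± 3.46 (SD, n = 4) and was above input only with the anchored scaling (adjusted p = 4.9e-06, against 0.609 with file totals). The 4 U6 regions ranged from 7.52 to 48.7, and 1 was above input with file totals and 4 with the anchored scaling. A U6atac gene on chromosome 2 (27395175 to 27395600) had 136.2 ± 59.0 (SD, n = 4) and was above input with either scaling (adjusted p = 0.00590 with file totals), with 0 in 1 input library; the list of type 3 genes, fixed beforehand, leaves it out. Both 7SL regions, beside Rps29 and Nemf on chromosome 12, were above input with either scaling (2 and 2 adjusted over the list alone), with 95.3 ± 12.8 and 124.7 ± 20.2 (SD, n = 4).

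Counts were also taken by chromosome, with no test between chromosomes. On chromosome 13, which holds 77 regions, 17 of 71 tested regions were above input with file totals and 60 of 75 with the anchored scaling. On chromosome 3, 5 of 35 and 21 of 35 were above. On chromosome 8, which holds the 5S genes, 1 of 61 was above input and 51 were below with file totals, and 57 of 61 were above with the anchored scaling. On chromosome 11, 15 of 30 and 23 of 29 were above, with a median coverage of 83.6. On chromosome 6, where many of the regions had low Pol III (median 1.22), the counts were 7 of 50 and 13 of 49. 87 regions that matched no gene were tested, and 9 were above input with file totals, while the anchored scaling gave 57 of 84. The cloverleaf search accepted 343 of 392 stretches with room for a single gene, so a missing match does not show that a gene is absent. The highest unmatched region, on chromosome 3 (90279632 to 90280003, 306 bp from the start of Ilf2), had 158.1 ± 33.8 (SD, n = 4) and was also chosen after its values were seen.

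The second comparison asked whether the Pol III subunits RPC1 and RPC4 gave the same picture. Regions ranked nearly alike (Spearman's rho 0.984 across 442 regions). With all 12 libraries in the fit, limma found 0 of 397 regions that differed, with 3 at an unadjusted p under 0.05, and no region could be named by the rule. A fit of only the 4 Pol III libraries, whose replicates varied less, called 30 regions, 15 higher in RPC1 and 15 higher in RPC4, by log2 differences of 0.29 to 1.01 in size. That fit used file totals and was not repeated with the anchored scaling. With all 12 libraries, the median log2 difference (RPC1 minus RPC4) was 0.0101 with file totals and -0.248 anchored. At the tRNA-Arg (TCG) region on chromosome 7, among the 30, it was 0.288 and 0.0168. The directions of small differences thus depend on the scaling. The median standard error of the difference was 0.57 in the fit of all libraries and 0.23 in the fit of 4. In occupied regions the median absolute log2 difference was 0.15. The absence of calls in the wider fit therefore does not show that the subunits were alike in every region.

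The third comparison concerned Pol II. RPB2 was above input in 30 of 397 regions and below in 124 with file totals. The anchored scaling gave 160 above and 1 below, median of ratios 40 and 9, and coverage as deposited 147 and 2. Without RPB2 replicate 1 the counts above and below input with file totals were 17 and 39, and with only RPB2 and input libraries in the fit 50 were above. The count below was 49 and 82 without input replicate 1 or 2, and 74 in windows of 150 bp around the summit. With file totals, the 5 largest folds fell in unlike places. The largest was at a tRNA-Glu (TTC) gene in an intron of Elf1 on chromosome 14 (79881325 to 79881696, 435 bp from the start of Wbp4), with RPB2 coverage of 32.3 ± 6.74 (SD, n = 2) and a log2 fold of 5.78 (SE 1.97, adjusted p = 0.0478). Its input coverage was 0.562 ± 0.795 (SD, n = 2), with 0 in 1 of the libraries, so this fold rests on the pseudocount. With the anchored scaling the RPB2 fold there was 6.10, below 7.31 beside Zfp259 and 6.61 nearest to Parp16. Its Pol III coverage was 82.5 ± 23.5 (SD, n = 4), which was not called with file totals (adjusted p = 0.0560) and was called with the anchored scaling (adjusted p = 1.46e-07). A region 212 bp from the start of Zfp259 on chromosome 9 (46080610 to 46081261) that matched no gene had RPB2 coverage of 146.3 ± 21.9 (SD, n = 2) and Pol III coverage of 4.78 ± 1.49 (SD, n = 4). Unmatched regions on chromosome 9 nearest to Parp16 and Slc38a3 had RPB2 coverage of 83.4 ± 46.3 and 64.4 ± 12.1 (SD, n = 2), and a tRNA-Arg (CCG) gene on chromosome 11 had 32.5 ± 2.25 (SD, n = 2).

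RPB2 was higher in occupied than in other regions. In the 88 occupied regions the median log2 enrichment of RPB2 over input was 0.56 and 0.58 in the 2 libraries, and in the 309 others it was -1.75 and -1.35. The others were not free of Pol III and held, for example, a tRNA-Met region with Pol III coverage of 231.0. The difference was 2.12 ± 0.27 (SD, n = 2), and 1.68 without division by input. Across the 88 occupied regions, RPB2 and Pol III enrichment had a Spearman's rho of 0.643, and 0.681 without division by input. Simulated libraries with no effect gave a mean rho of 0.870 through the shared input alone. The covariance was 0.457 against 0.137 simulated, a difference of 0.320, and part of any excess may come from the shared input. With Pol III divided by 1 input library and RPB2 by the other, added after seeing the data, the mean rho of both assignments was 0.303 and the covariance 0.305. The RPB2 maximum lay a median of 67.3 ± 2.47 bp (SD, n = 2) from the Pol III summit, against 140.3 ± 22.3 bp (SD, n = 2) in input. Regions above input for RPB2 with file totals and also occupied numbered 22 (6.65 for independent lists), or 29 (21.5) with anchored occupancy. Simulated libraries with no difference held 0 Pol III calls, so they give no overlap to compare with, and part of the excess may come from the shared input.

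The fourth comparison concerned the H3K4-titled libraries. 50 of 397 regions were above input and 235 below with file totals. The anchored scaling gave 257 above and 19 below, median of ratios 93 and 131, and coverage as deposited 144 and 123. Without H3K4-titled replicate 1 the count above input with file totals was 32. The anchored count below was 40 without H3K4-titled replicate 2 and 10 without either input library. The tRNA-Glu (TTC) gene in Elf1 again had the largest fold, with the same limit from input and with coverage of 89.0 ± 32.3 (SD, n = 2) and a log2 fold of 6.79 (SE 1.97, adjusted p = 0.0138). A tRNA-Arg (TCT) gene on chromosome 3 (121995716 to 121996100) had 54.1 ± 26.2 (SD, n = 2), and an unmatched region nearest to Klrb1c on chromosome 6 (128709861 to 128711030) had 75.2 ± 12.8 (SD, n = 2) with adjusted p = 3.86e-05. A tRNA-Thr (CGT) gene on chromosome 13 and a tRNA-Leu (TAG) gene on chromosome 14 had 13.4 ± 4.2 and 9.58 ± 2.6 (SD, n = 2). Input was 0 in 1 library at both, so these folds too rest on the pseudocount, and with the anchored scaling they were 7.90 and 7.38, below 9.20 at the tRNA-Arg and 9.22 at the Klrb1c region.

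H3K4-titled signal separated occupied from other regions more than RPB2 did. The median log2 enrichment was 0.92 and 0.90 in the 2 libraries over occupied regions and -3.32 and -3.00 over the others, a difference of 4.07 ± 0.25 (SD, n = 2). H3K4-titled coverage was 0 in 102 and 70 of 532 stretches, against 4 and 6 for RPB2. The size of its difference thus depends in part on the pseudocount, and was 3.81 with that doubled (2.06 for RPB2). Within occupied regions H3K4-titled signal followed the level of Pol III only loosely, with a rho of 0.178, or 0.271 without division by input, against a simulated 0.903. The covariance was 0.180 against 0.141 simulated, a difference of 0.0387. With each divided by another input library the mean rho was 0.0728 and the covariance -0.18. This rho rested on the input: it was 0.536 without input replicate 1 and 0.114 without input replicate 2. Across the 284 regions occupied by the anchored scaling it was 0.718. The H3K4-titled maximum lay a median of 177 ± 2.12 bp (SD, n = 2) from the Pol III summit, against 140.3 bp in input. It lay within 25 bp of a stretch end, where coverage stops, in 53 of 88 and 62 of 86 occupied regions with coverage (21 of 88 and 20 of 83 in input), so this distance is a lower bound. Regions above input for H3K4-titled signal and also occupied numbered 40 (11.1 for independent lists), or 49 (35.8) with anchored occupancy, and part of the excess may come from the shared input.

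**Figure D3:**
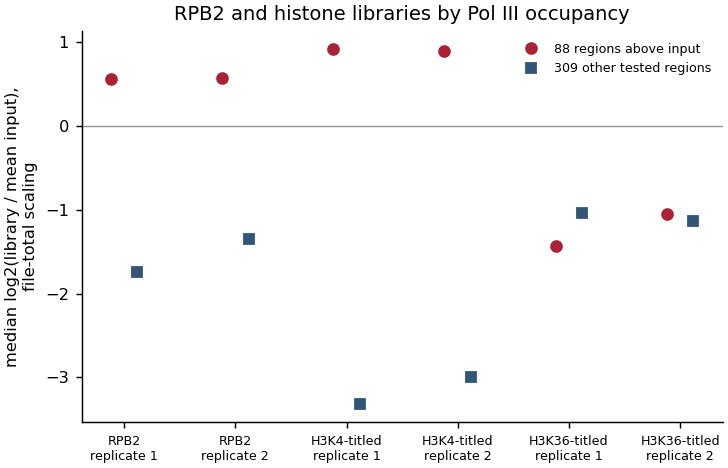
Median log2 ratio of each RPB2, H3K4-titled and H3K36-titled library to mean input (file-total scaling) in the 88 regions occupied by Pol III (circles) and in the 309 other tested regions (squares). Both RPB2 and both H3K4-titled libraries were higher in occupied regions, while the H3K36-titled libraries differed in opposite directions.

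The fifth comparison concerned the H3K36-titled libraries, which held the fewest reads over these stretches. 16 of 397 regions were above input and 110 below with file totals. The anchored scaling gave 16 above and 34 below, median of ratios 32 and 29, and coverage as deposited 12 and 276. The count below with file totals was 54 and 57 without input replicate 1 or 2, 169 without H3K36-titled replicate 1 and 26 with only H3K36-titled and input libraries in the fit. Without input replicate 1 the anchored counts above and below input were 10 and 12, and without H3K36-titled replicate 1 the anchored count below was 56. Of the 16 regions, 12 lay inside annotated genes (75%), against 88 of the other 381 tested regions (23.1%), and 0 of the 16 were occupied by Pol III with file totals (3.55 for independent lists) and 6 with the anchored scaling (11.4 for independent lists). The largest fold was at a tRNA-Val (AAC) gene in an intron of Ubr4 on chromosome 4 (138986271 to 138986642), with H3K36-titled coverage of 13.6 ± 1.77 (SD, n = 2), Pol III coverage of 0.863 ± 0.315 (SD, n = 4), and a log2 fold of 4.63 (SE 0.72, adjusted p = 0.00163). The other 4 named regions were unmatched regions in an intron of Dhx9 (chromosome 1), an exon of Cdkn2aipnl (chromosome 11) and an intron of Dhdh (chromosome 7), and a tRNA-Asp (GTC) gene in an intron of Aqr (chromosome 2). Their H3K36-titled coverage was 13.1 ± 6.38, 14.0 ± 5.84, 7.09 ± 0.264 and 4.81 ± 0.741 (SD, n = 2).

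For H3K36-titled signal the log2 differences between occupied and other regions were -0.40 in replicate 1 and 0.087 in replicate 2, with a mean of -0.16 ± 0.35 (SD, n = 2), and -0.50 without division by input. With anchored occupancy the difference was -0.43 ± 0.14 (SD, n = 2; -0.33 and -0.53). The rho with Pol III was 0.295, or 0.276 without division by input, against a simulated 0.508, and the covariance was 0.455 against 0.139 simulated, a difference of 0.316. With each divided by another input library the mean rho was 0.136 and the covariance 0.333. The rho was 0.561 without input replicate 1 and became -0.139 across the 284 regions occupied by the anchored scaling.

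Over single tRNA genes with Pol III above input by the anchored scaling (168 stretches), the libraries had different shapes. Pol III coverage over the gene was 3.29 to 4.16 times that of the outer 50 bp of both flanks in the 4 libraries. H3K4-titled coverage over the gene was 0.321 and 0.332 times that of the flanks, and gene coverage was the lower in 124 and 130 of 168 stretches. The ratio was 1.5 in both RPB2 libraries and 1.03 in both input libraries. These 168 stretches were chosen with a scaling added after the data had been seen.

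**Figure D4:**
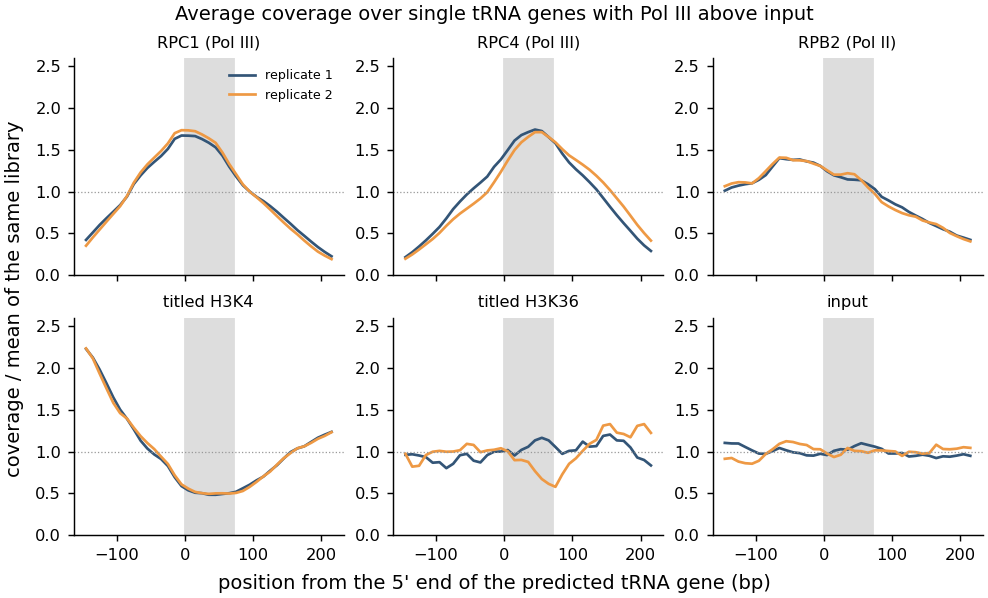
Mean coverage along 168 single tRNA genes with Pol III above input by the anchored scaling, divided by the same library's mean, against position from the predicted 5' end (bp), 1 line per replicate. Grey marks the first 72 bp of the gene. RPC1 peaks near the 5' end of the gene, RPC4 inside it and RPB2 upstream of it. H3K4-titled signal dips over the gene, and input is nearly flat.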

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

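Scaling by background, unscaled coverage, divided input libraries, and occupied regions taken from the anchored scaling were chosen after the data had been seen. For 13 results, 188 alternatives were computed, 135 planned and 53 added. 106 stayed within 1.5 times (counts) or within the spread between libraries (other values), and 2 changed sign. The cause of these changes was not tested, except that a scaling sets the zero of every fold.

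Regions with more Pol III than input numbered 88, and 284 with the anchored scaling, 289 as deposited, 284 anchored with a replicate block and 327 anchored with merging under 200 bp. Leaving out 1 library gave 72 to 79, or 265 to 280 when anchored (278 without either RPC1 library, 279 without RPC4 replicate 1, 276 without input replicate 1). RPC1 and RPC4 differed in 0 regions with limma (3 at an unadjusted p under 0.05), in 0 without any library, and in 30 when only those groups were fitted. For RPB2 the 30 regions became 50 with only the groups compared, 160 anchored, 147 as deposited, 162 anchored with a replicate block and 187 anchored with merging under 200 bp. Leaving out 1 library gave 17 (without RPB2 replicate 1) to 31, or 131 to 184 anchored (138 without RPB2 replicate 2). For H3K4-titled signal the 50 regions became 93 with median of ratios, 257 anchored, 144 as deposited, 257 anchored with a replicate block and 298 anchored with merging under 200 bp. Leaving out 1 library gave 32 (without H3K4-titled replicate 1) to 45, or 238 to 265 anchored (252 without input replicate 1). For H3K36-titled signal the 16 regions became 32 with median of ratios and 10 with only the groups compared. Leaving out 1 library gave 12 to 23, or 10 (without input replicate 1) to 20 anchored.

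No pairing of libraries by replicate number was seen, with correlations of replicate differences between groups of -0.104 to 0.0959. Noise in libraries with few reads may hide a pairing by collection. With the replicate block the counts above input were 86 for Pol III, 28 for RPB2, 52 for H3K4-titled and 14 for H3K36-titled, with 0 between RPC1 and RPC4.

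The RPB2 difference between occupied and other regions, 2.12, was 1.68 without division by input, 2.41 in windows of 150 bp around the summit, 2.67 between highest and lowest Pol III regions and 1.71 with anchored occupancy, and 1.93 to 2.31 without 1 library. The H3K4-titled difference, 4.07, was 3.76, 3.46, 5.32 and 3.28 in the same order, 3.81 with a doubled pseudocount, and 3.82 to 4.32 without 1 library. The H3K36-titled difference, -0.16, was -0.75 in windows, -0.69 between highest and lowest Pol III regions, and -0.40 to 0.087 without 1 library, where leaving out H3K36-titled replicate 1 changed its sign.

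The rho of Pol III with RPB2, 0.643, was 0.681 without division by input, 0.663 with RPC1 alone, 0.598 with RPC4 alone, 0.721 with anchored occupancy, 0.303 with each divided by another input library, and 0.608 to 0.762 without 1 library. That with H3K4-titled signal, 0.178, was 0.271, 0.223, 0.135, 0.718 and 0.0728 in the same order, 0.395 in windows, and 0.114 (without input replicate 2) to 0.536 (without input replicate 1). That with H3K36-titled signal, 0.295, was 0.276 without division, 0.317 with RPC1 alone, 0.373 in windows, 0.136 with each divided by another input library, 0.215 to 0.561 (without input replicate 1), and changed sign to -0.139 with anchored occupancy.

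The RPB2 distance, 67.3 bp, was 52.8 bp with smoothing over 150 bp, 54 bp from the RPC1 summit, 74.8 bp from the RPC4 summit, 59 bp with anchored occupancy, and 65.5 to 69 bp in single libraries. The H3K4-titled distance, 177 bp, was 180.8, 171, 180.5 and 161 bp in the same order, and 175.5 to 178.5 bp in single libraries. Stretch ends limit the H3K4-titled distances.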

Other observations

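The tests of open chromatin, of recovery of Pol III by the RPB2 antibody, of exchanged titles and of shared 5S reads, and the comparison of flanks, were chosen after the result was seen, while the tests of promoters close by, closeness to starts and CpG content were not.

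RPC1 and RPC4 lay differently along tRNA genes. Over 168 single tRNA genes with Pol III above input by the anchored scaling, RPC1 coverage in the outer 50 bp upstream was 1.73 and 1.85 times that downstream in the 2 libraries, and RPC4 coverage was 0.781 and 0.510 times. The upstream to downstream ratio of RPC1 exceeded that of RPC4 in 150, 158, 152 and 153 of these genes for the 4 pairs of libraries, against 45, 35, 51 and 42 of 87 tRNA genes not called above input by that scaling. The RPB2 ratio was 2.20 and 2.31, the H3K4-titled ratio 1.69 and 1.68, and the input ratio 1.13 and 0.854. In the 87 genes not called these ratios were 1.24 and 1.81 for RPC1, 1.20 and 1.38 for RPC4, 1.68 and 1.32 for RPB2, 0.707 and 1.06 for H3K4-titled signal, and 1.16 and 1.70 for input. These 87 genes were not free of Pol III signal: coverage over the gene was 1.27 and 1.14 times that of the flanks for RPC1 and 1.52 and 1.40 times for RPC4, against 0.825 and 0.862 times in input.

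RPB2 coverage was higher in regions occupied by Pol III than in others, by 1.68 on the log2 scale without division by input. Easier recovery of open chromatin before the precipitation is argued against by the input libraries. Input skips the precipitation and cannot show unspecific recovery in that step, which stays open. Between the 132 regions with the highest and the 132 with the lowest Pol III coverage, input differed by -0.20 (-0.50 and 0.11 in single libraries) and RPB2 by 2.49 without division by input. This split replaced an earlier one between occupied and other regions, which are called against the same input. Annotated protein-coding promoters within 5 kb are argued against as the whole cause. Over regions more than 5 kb from a protein-coding start the RPB2 difference was 1.54 (1.39 and 1.68 in single libraries). Distances were taken to annotated protein-coding starts only, so other Pol II promoters close by stay open. Recovery of Pol III by the RPB2 antibody stays open, and the shape of coverage along single tRNA genes cannot decide it. Over 121 of them that far from a start, occupied by the anchored scaling, mean RPB2 coverage upstream was 2.28 and 2.77 times that downstream. The ratio was 1.58 and 1.701 for RPC1, 0.723 and 0.482 for RPC4, and 1.197 and 0.87 for input. Gene counts did not show this excess: upstream was higher in 101 and 96 of all 168 for RPB2, and 114 and 109 for RPC1. RPC1 and RPC4 are both subunits of Pol III yet differed in the mean ratio, so RPB2 signal from recovered Pol III need not match either. Such recovery predicts that RPB2 follows the level of Pol III. Over 52 occupied regions that far from a start, RPB2 followed Pol III coverage with a rho of 0.675 (0.665 and 0.685). Pol II at the Pol III genes themselves may give the same relation and stays open.

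For the 4 histone libraries, whose title and antibody field disagree, exchanged titles are argued against. The H3K4-titled libraries were higher within 1 kb of a protein-coding start than over 10 kb away by 3.44 and 3.06 on the log2 scale, and the H3K36-titled libraries by -0.36 and -0.01. The smallest gap between them was 3.07, which argues against the antibody fields as they stand.

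The 5S rRNA genes had nearly equal Pol III coverage, with a coefficient of variation of 25.7% over 50 stretches against 123.2% over tRNA stretches. Reads shared between near-identical copies may account for it, since 98.0% of the bases in 5S stretches had fractional coverage, against 9.84% elsewhere. Equal occupancy of the copies stays open, as shared reads cannot separate them.

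A hypothesis is that Pol III occupancy of these genes goes with closeness to Pol II promoters and with CpG content. Of occupied regions, 28.4% (25 of 88) lay within 2 kb of a protein-coding start, against 11.3% (35 of 309) of the others (one-sided permutation test within chromosomes, p = 0.01408, and 0.01886 without 5S regions). The share of regions above input was 41.7% within 2000 bp, 42.3% from 2000 to 5000 bp, 29.5% from 5000 to 20000 bp and 7.69% beyond with file totals, and 95.0%, 76.9%, 74.4% and 59.3% with the anchored scaling. Among regions over 5 kb from a start, the median ratio of observed to expected CpG was 0.815 in 52 occupied and 0.571 in 259 other regions (one-sided permutation test, p = 1e-05, the smallest these permutations can give), and 0.419 in the others without 5S regions. With anchored occupancy the medians were 0.776 in 204 occupied and 0.175 in 107 other regions (one-sided permutation test, p = 1e-05). Both relations may follow from how these genes were placed or kept in the genome, which was not tested, and regions in a cluster are not independent.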
